A study of Homo sapiens with 6 samples.

How the data were processed

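RNA of 6 libraries, 3 labelled control and 3 labelled knockdown, was measured by sequencing, and 1 deposited table gives 1 value per gene and library. The authors deposited these values as RPKM, as the table's name and the labels' description field state. Per the submitters' processing notes, HISAT2 and GRCh38 were used. The read counter, its annotation and any filter are not given in the sources used here. All 58676 gene IDs of the table were found in GENCODE release 29 (GRCh38), from which symbols, coordinates, exon lengths and 3' UTRs were taken. The labels' protocols describe Trizol extraction and standard library preparation, and whether counting used strand is not stated, so overlapping and antisense genes cannot be told apart.

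The low RPKM values were used to find the depth. In 5 libraries the RPKM value times the gene's summed exon length was a whole multiple of 1 step for 100% of the values above 0 (tolerance 0.002 of a read), and the multiples were read as assigned reads. They sum to 9181567, 1948940 and 19605312 reads in control replicates 1, 2 and 3 and to 9296308 and 15198231 in knockdown replicates 1 and 3. Control replicate 2 is the shallowest of them, and the first principal component (66.5% of the variance) sets it apart from the other 4. In knockdown replicate 2, 0.285% of the values were whole under the gene ID of their row. Mitochondrial transcripts took 7.40%, 10.4% and 4.94% of reads in the controls and 8.30% and 7.83% in knockdown replicates 1 and 3. No pair of these 5 libraries shared a value above 0 at any gene, so none was deposited more than once.

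The test fixed before the data were examined was limma (lmFit and eBayes with a mean-variance trend) on log2(RPKM + 0.5), two-sided, over genes at 0.5 RPKM or more in at least 3 libraries, with Benjamini-Hochberg adjusted p under 0.05, on all 6 columns without covariates. Since knockdown replicate 2 did not follow the gene IDs, the fit without it, one of the alternatives planned, was used for levels and named genes. That was decided after the rank correlations were seen, before calls were compared. It leaves 3 control and 2 knockdown libraries. Values of that column as deposited enter the comparison of the 6 columns, the alternatives that hold it and the listing of the miR-19 genes at 0, and no other level of a named gene.

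The 37 gene lists and the gene rule were fixed before the data were examined. The rule names MIR17HG always, the genes of largest fold change among those past the threshold with separated groups, and, where fewer than 5 pass in a direction, the 5 of largest moderated statistic in that direction. It was written for the 6 columns, where it leads to MIR1244-3, MIR6812, RNY3P16, AC037487.3 and RNA5S9 as higher and SNORA80E, DSTNP1, AL139161.1, RF00019 and SNORA28 as lower, and it was applied to the 5 libraries because values of the sixth column did not follow the gene IDs. The rule names no list member when none passes, so members named from lists, most of them those of smallest unadjusted p in the list's direction, were chosen after their values were seen. Some genes that the rule or the lists would name are not reported here. Lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Sites were searched in the longest annotated 3' UTR of 19133 coding genes. Genes with the site were compared, within 10 bins of 3' UTR length, with genes lacking it and its first 6 bases, TTTGCA. Genes holding TTGCAC, the site without its first base, were not taken out of the comparison group. An exact permutation over splits of the libraries and the same difference for the 419 other orders of the site's bases used these bins, and camera did not.

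Alternatives were other pseudocounts (0.1 and 1), filters, scalings (an unweighted trimmed mean of log ratios, median ratios, quantiles), no mean-variance trend, a minimum log2 fold change of 1, the replicate number as a block, and leaving out each library. Chosen after seeing the data were the same alternatives on 5 libraries, limma voom on the recovered reads with and without sample weights, thinning of the 5 libraries to the depth of control replicate 2, removal of each library's trend against exon length and GC content (a value for 100% of genes), and a re-ordering of knockdown replicate 2. TMM here means the unweighted form.

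The code was tested on simulated data drawn for the real genes and depths of the 3 control and 2 knockdown libraries. Over 15657 genes tested, with 200 changed, 75.8% of genes changed 4-fold and 8.08% of genes changed 2-fold were called, and 0 unchanged genes. All simulated genes had 1 dispersion (0.022), so these shares need not hold in the measured libraries. There DUOX2, at 0.959 RPKM in control and 3.98 RPKM in knockdown, did not pass (limma adjusted p = 0.71). A list shifted by 0.5 came back with a median of 0.52. Site genes shifted by 0.2 came back at 0.17 on average over 10 draws (0.16 to 0.18), and at 0.18 without noise, since the pseudocount shrinks low genes. With no change the site difference lay between -0.02 and 0.01. Simulated genes varied independently and without trends against length or GC, so this range does not measure the spread between the real libraries. Among those, another split of the 5 libraries gave a difference of 0.0777 in size. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.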

Results

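Total RNA of a human cell line labelled HCC was sequenced in 6 libraries, 3 labelled control and 3 labelled knockdown. The labels of the knockdown libraries name a sponge and the series title names miR-19a. A sponge is a transcript that carries binding sites for a microRNA and so takes it up. The cell line itself is not named, and the title speaks of treated cells while the design text speaks of a knockdown, so the direction of the treatment is taken from the group labels. The values were RPKM, reads scaled by the length of the gene's exons and by the library's assigned reads. Reads assigned to genes, recovered from the RPKM values, came to 9181567, 1948940 and 19605312 in control replicates 1, 2 and 3, and to 9296308 and 15198231 in knockdown replicates 1 and 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

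The values of knockdown replicate 2 did not follow the gene IDs of their rows. Spearman's rank correlation across genes was 0.82 to 0.89 between any pair of the other 5 libraries, and 0.017 to 0.019 between knockdown replicate 2 and each of them. Genes are not independent replicates, and these correlations describe the columns only. The comparison was therefore fitted with all 6 columns as deposited and without knockdown replicate 2, and, unless stated, values are given for the 5 libraries that followed the gene IDs.

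**Figure D1:**
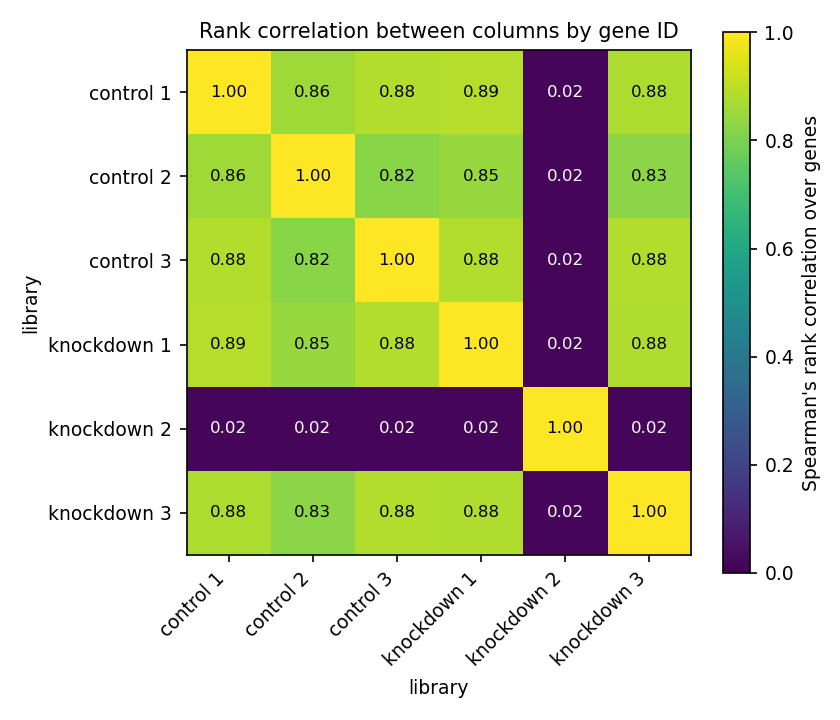
Spearman's rank correlation across all genes between each pair of the 6 columns, matched by gene ID, with each library on both axes and the color scale running from 0 to 1. Knockdown replicate 2 correlated at 0.017 to 0.019 with the other 5 columns, which correlated at 0.82 to 0.89 with each other.

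The comparison of knockdown with control asked what lower availability of miR-19 does to messenger RNA levels. The microRNA genes themselves gave no check of the labels, since MIR19A, MIR19B1 and MIR19B2 were listed at 0 in all 6 columns, knockdown replicate 2 as deposited included, and a sponge need not change the level of its target. MIR17HG (ENSG00000215417), the host transcript of the miR-17-92 cluster on chromosome 13 from 91347820 to 91354579 of GRCh38, was at 0.811, 0.441 and 1.24 RPKM in the controls and at 1.26 and 1.13 RPKM in knockdown replicates 1 and 3. These values rest on 26, 3, 85, 41 and 60 reads, and the log2 difference of 0.39 (SE 0.32) did not pass (limma adjusted p = 0.77) and was 0.17 without control replicate 2 and 0.61 without control replicate 3.

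Glycolysis and hypoxia genes, and NF-kB and inflammatory genes, were higher in knockdown replicates 1 and 3 than in the 3 controls. Of 25 hypoxia list members tested, 24 had a log2 difference above 0, with a median of 0.53, and 10 rose when adjusted over the list alone against 0 over all genes. CA9 (ENSG00000107159, chromosome 9 from 35673856 to 35681159), a carbonic anhydrase induced by low oxygen, was at 7.20 ± 0.816 RPKM (SD, n = 3) in control and 16.6 ± 1.94 RPKM (SD, n = 2) in knockdown, a log2 difference of 1.15 (SE 0.17). The glycolytic enzymes ENO2 and ALDOC differed by 1.01 (SE 0.17) and 0.74 (SE 0.14), and NDRG1, a gene induced by hypoxia, by 0.92 (SE 0.17). All 19 tested members of the NF-kB list were above 0, with a median of 0.72, and 7 rose when adjusted over the list alone. The median was 0.48 without control replicate 2. RELB and NFKB2, subunits of NF-kB, were 1.15 (SE 0.20) and 0.73 (SE 0.13) higher. NFKBIA, its inhibitor, was 0.83 (SE 0.16) higher, and BIRC3, an inhibitor of apoptosis, 1.29 (SE 0.27) higher. Interferon response genes were above 0 for 13 of 14 members, with a median of 0.44, and IFI6 at 1.06 (SE 0.21) was the single member that rose when adjusted over the list alone. With camera at its preset correlation the adjusted p was 1.98e-14 for hypoxia, 1.14e-10 for NF-kB and 0.000234 for interferon response. These calls were lost with an estimated correlation, where the adjusted p was 0.117 for hypoxia, 0.445 for NF-kB and 0.474 for interferon response. With fry the hypoxia list passed (adjusted p = 0.0133) and the NF-kB list did not (adjusted p = 0.213), nor did the interferon list (adjusted p = 0.216).

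DNA replication and cholesterol synthesis genes were lower in the same libraries. Of 26 DNA replication genes, 24 were below 0, with a median of -0.36, and 0 passed when adjusted over the list alone or over all genes. UHRF1, which maintains DNA methylation at replication, was at 19.5 ± 0.352 RPKM (SD, n = 3) in control and 12.7 ± 1.35 RPKM (SD, n = 2) in knockdown, a log2 difference of -0.60 (SE 0.14). MCM6 and MCM2, subunits of the replicative helicase, differed by -0.57 (SE 0.16) and -0.75 (SE 0.21), and CDC6, which loads that helicase, by -0.58 (SE 0.16). Of 22 cholesterol synthesis genes, 21 were below 0, with a median of -0.41, and 0 passed when adjusted over the list alone. HMGCS1, the enzyme that makes HMG-CoA, went from 204.7 ± 14.2 RPKM (SD, n = 3) to 101.8 ± 21.4 RPKM (SD, n = 2), a log2 difference of -1.02 (SE 0.20), and CYP51A1, an enzyme of the same pathway, differed by -1.12 (SE 0.38). Fatty acid synthesis and lipid storage genes were below 0 for 16 of 20 members, with a median of -0.30, and FASN, the fatty acid synthase, at -0.63 (SE 0.19). GPAM, which starts glycerolipid synthesis, was at 4.04 ± 0.693 RPKM (SD, n = 3) in control and 1.77 ± 0.427 RPKM (SD, n = 2) in knockdown. Cell division genes were below 0 for 26 of 28 members, with a median of -0.28, and MKI67, a marker of dividing cells, at -0.74 (SE 0.21). In this list the groups overlapped, with control replicate 2 at -0.29 and knockdown replicate 1 at -0.24, and the median was -0.11 without control replicate 3 and -0.44 without control replicate 2. Their camera adjusted p was 2.04e-08 for DNA replication, 3.86e-08 for cholesterol synthesis, 0.000639 for fatty acid synthesis and 4.35e-05 for cell division. With an estimated correlation none of these 4 passed, with an adjusted p of 0.445 for the first 3 lists and 0.551 for cell division.

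**Figure D2:**
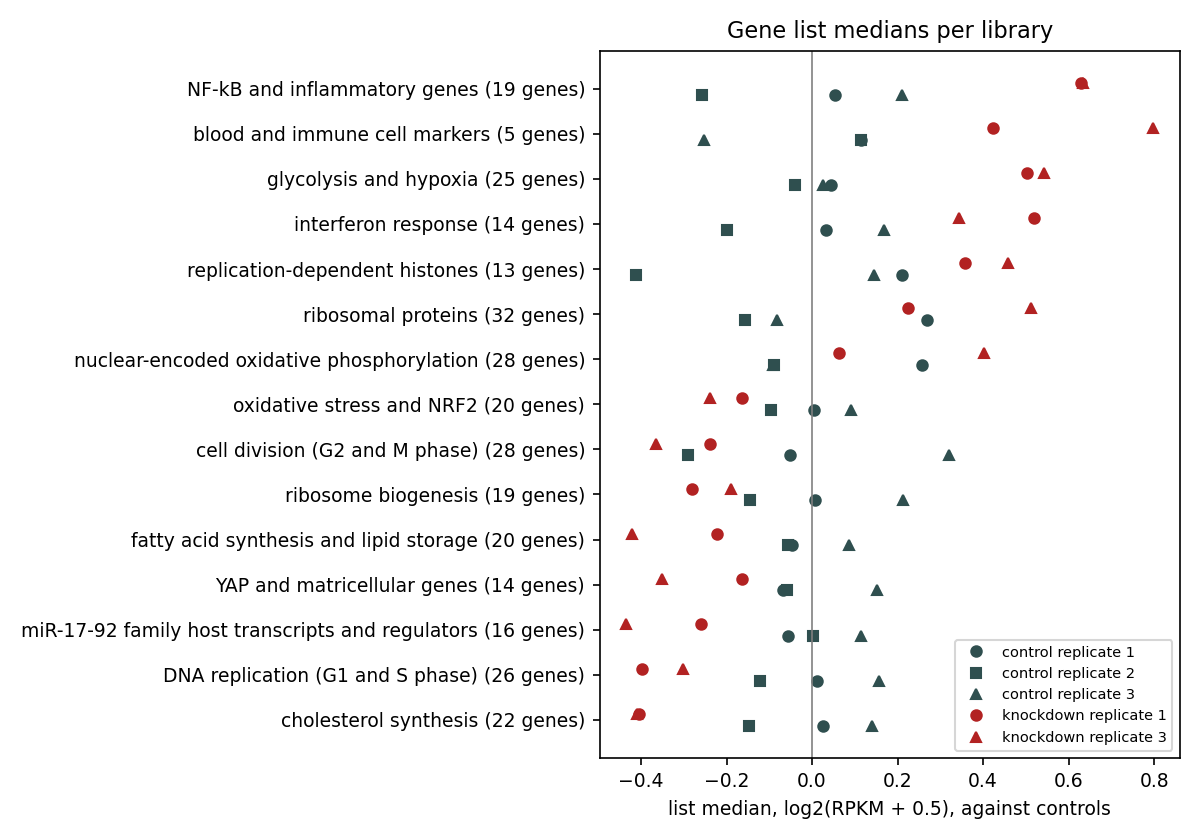
Median over list members of the log2(RPKM + 0.5) difference from the mean of the 3 controls, with 1 point per library, for the 15 lists that passed camera at its preset correlation without knockdown replicate 2. For the hypoxia list the knockdown libraries sit at 0.50 and 0.54 and the controls between -0.04 and 0.04, while the groups overlap for ribosomal proteins (control replicate 1 at 0.27, knockdown replicate 1 at 0.23), oxidative phosphorylation (0.26 and 0.06) and cell division (control replicate 2 at -0.29, knockdown replicate 1 at -0.24).

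**Figure D3:**
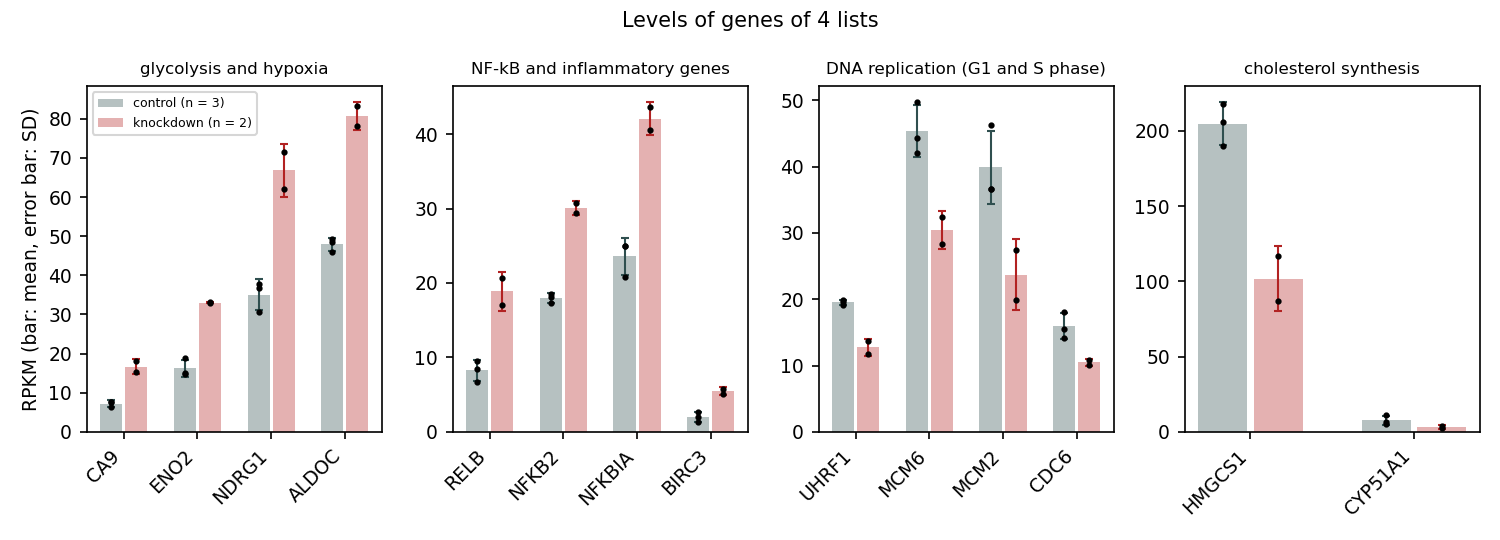
RPKM of members among those with the smallest unadjusted p in the list's direction, for each of 4 lists, with 1 point per library, bars at the mean and error bars of 1 SD, for 3 control and 2 knockdown libraries. CA9 averages 7.20 RPKM in control and 16.6 RPKM in knockdown, and HMGCS1 averages 204.7 and 101.8 RPKM.

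Further lists passed camera at its preset correlation and none of them with an estimated one. Ribosomal proteins were above 0 for 32 of 32 members, with a median of 0.37 (adjusted p = 9.05e-07, and adjusted p = 0.551 with an estimated correlation), and RPS19 at 0.68 (SE 0.26). In this list control replicate 1 lay above knockdown replicate 1, at 0.27 against 0.23, and the median was 0.23 without knockdown replicate 3. Nuclear-encoded oxidative phosphorylation genes were above 0 for 22 of 28 members, with a median of 0.24 (adjusted p = 0.0189, and adjusted p = 0.734 with an estimated correlation), and here too control replicate 1 at 0.26 lay above knockdown replicate 1 at 0.06. This call ended without control replicate 3 (median 0.12, adjusted p = 0.516) and without knockdown replicate 3 (median 0.06, adjusted p = 0.561), and the median was 0.40 without knockdown replicate 1. Replication-dependent histones were above 0 for 11 of 13 members, with a median of 0.41 (adjusted p = 0.0141, and adjusted p = 0.635 with an estimated correlation). The median was 0.28 (adjusted p = 0.124) with trends against gene length and GC removed. Without control replicate 2 it was 0.21 (adjusted p = 0.0473), and the call ended without knockdown replicate 1 (median 0.45, adjusted p = 0.0536). Host transcripts and regulators of the miR-17-92 family were below 0 for 13 of 16 members, with a median of -0.34 (adjusted p = 0.000547, and adjusted p = 0.474 with an estimated correlation), and MYCN, a transcription factor, fell when adjusted over the list alone, from 5.76 ± 0.784 RPKM (SD of 3 libraries) to 2.62 ± 0.383 RPKM (SD of 2 libraries). Ribosome biogenesis genes were below 0 for 16 of 19 members, with a median of -0.29 (adjusted p = 0.000733, and adjusted p = 0.538 with an estimated correlation), or -0.19 without either control replicate 3 or knockdown replicate 1. The NRF2 list was below 0 for 16 of 20 members, with a median of -0.18 (adjusted p = 0.00504, and adjusted p = 0.445 with an estimated correlation), and NQO1 at -0.53 (SE 0.15). This call ended without knockdown replicate 1 (median -0.24, adjusted p = 0.0743), while the median was -0.29 without control replicate 2. YAP and matricellular genes were below 0 for 11 of 14 members, with a median of -0.31 (adjusted p = 0.0284, and adjusted p = 0.538 with an estimated correlation). This call ended without control replicate 2 (median -0.25, adjusted p = 0.0900), control replicate 3 (median -0.27, adjusted p = 0.0819) or knockdown replicate 3 (median -0.16, adjusted p = 0.114). Blood and immune cell markers, 5 genes of which 4 were above 0, had a median of 0.63 (adjusted p = 0.0189, and adjusted p = 0.489 with an estimated correlation), or of 0.51 (adjusted p = 0.107) without control replicate 3. Their most abundant members did not move together, with CD3D at 3.08 to 4.46 RPKM in control and 6.09 to 6.14 RPKM in knockdown, and CD14 at 28.6 to 38.4 RPKM in control and 30.6 to 36.8 RPKM in knockdown. The fibroblast and endothelial lists had 4 and 1 tested members and were not tested. LUM, a fibroblast marker, was at 54.2 to 68.2 RPKM in control and 53.5 to 54.5 RPKM in knockdown. The collagen genes COL1A2 (7.54 to 11.7 RPKM in control, 12.02 to 14.72 RPKM in knockdown) and COL1A1 (0.732 to 1.99 and 2.16 to 2.33 RPKM) lay above all 3 controls in both knockdown libraries, and PDGFRA (0.580 to 1.11 and 0.352 to 0.431 RPKM) below them. The remaining 20 tested lists did not pass.

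Across genes, the log2 difference had a Spearman correlation of -0.23 with exon length and 0.27 with GC content over 15408 genes, which are not independent replicates. With each library's trend against length and GC removed, the medians were 0.55 for hypoxia, 0.56 for NF-kB, -0.42 for DNA replication and -0.43 for cholesterol synthesis.

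By the rule fixed for single genes, those with the largest moderated statistics are named although none passed, at an adjusted p of 0.71 in limma without knockdown replicate 2. Higher in knockdown were PSMB9, an immunoproteasome subunit on chromosome 6 from 32844136 to 32859585, at 0.395 ± 0.0946 RPKM (SD, n = 3) in control and 3.66 ± 1.01 RPKM (SD, n = 2) in knockdown, a log2 difference of 2.20 (SE 0.26), and DUOX2, an oxidase that makes hydrogen peroxide, at 1.61 (SE 0.21). The long noncoding RNA AC026401.3 differed by 1.37 (SE 0.18), the neuropeptide NPY by 1.24 (SE 0.16), and UBE2L6, an interferon-induced enzyme that conjugates ISG15, by 1.32 (SE 0.19). Lower were SLC1A3, a glutamate transporter on chromosome 5 from 36606355 to 36688334, at 6.33 ± 0.490 RPKM (SD, n = 3) in control and 2.11 ± 0.221 RPKM (SD, n = 2) in knockdown, a log2 difference of -1.39 (SE 0.17), and the calcium channel gene TRPC4 at -1.02 (SE 0.17). SPP1, which encodes osteopontin, differed by -0.97 (SE 0.17) and the long noncoding RNA AC131532.1 by -1.02 (SE 0.19). The pseudogene DSTNP1 had 4, 1 and 9 reads in the controls and 0 in the knockdown libraries, at least 3.83-fold lower against a floor of 3 reads over the group, and is uncertain because a pseudogene can share reads with its parent. Fold changes are on the log2(RPKM + 0.5) scale and understate changes of low genes. With voom and sample weights PSMB9, DUOX2, UBE2L6 and SLC1A3 passed. With the replicate number as a block in limma, PSMB9 (adjusted p = 0.0116) and UBE2L6 (adjusted p = 0.0306) passed, at 1 residual degree of freedom.

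With all 6 columns as deposited, limma called 0 of 15683 genes higher and 0 lower, and 53 and 31 genes had an unadjusted p under 0.05, 84 in all against up to 324 in the 9 other splits of the columns. The median log2 difference of all genes was -0.91 there and 0.00 without knockdown replicate 2. Of 35 gene lists, cholesterol synthesis alone passed with camera at its preset correlation of 0.01 (adjusted p = 0.0151), and its adjusted p was 0.914 with an estimated correlation. Without knockdown replicate 2, limma again called 0 of 15408 genes higher and 0 lower at an adjusted p under 0.05, with 585 and 392 genes at an unadjusted p under 0.05, 977 in all against 1063 when control replicates 1 and 2 were set against the rest. The lowest adjusted p was 0.71. On reads recovered from the RPKM values, voom also called 0 genes, with 747 higher and 885 lower at an unadjusted p under 0.05, and voom with sample weights called 3 higher and 1 lower. Both knockdown libraries lay above all 3 controls for 2199 genes and below all of them for 2089, together 27.8% of genes against the 20% that chance gives for 3 against 2 libraries and up to 24.99% in the 9 other splits of the 5 libraries.

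Genes with a miR-19 site in the 3' UTR, the match TTTGCAC to the microRNA seed, tested whether site-bearing transcripts differed from the rest. Within bins of 3' UTR length, 1795 genes with a site differed in median log2 change by -0.0781 from 6246 genes without it or TTTGCA. Those 6246 genes could still hold TTGCAC, the site without its first base. The 802 genes with the longer 8-base site differed by -0.0847. Over the 10 splits of the 5 libraries the two-sided exact permutation p was 0.1, the smallest these splits allow, with the next split at 0.0777 in size, and over the 10 splits of the 6 columns it was 0.2 for a difference of -0.0624. Camera was run on these genes without the bins, where the medians were -0.0937 with a site and 0.0636 without one. It gave p = 6.36e-06 at its preset correlation and p = 0.441 with an estimated correlation. These p-values therefore do not test the binned difference and leave 3' UTR length uncorrected. The binned difference was -0.0348 with each library's trend against exon length and transcript GC removed, -0.0488 without control replicate 3 and -0.0459 without knockdown replicate 3. Of 25 tested published miR-19 targets, 12 were above 0 and 13 below, with a median of -0.14 and an adjusted p of 0.434 in camera (adjusted p = 0.842 with an estimated correlation), and the median was -0.31 without knockdown replicate 1 and 0.08 without knockdown replicate 3. At an unadjusted p under 0.05 in limma, 3 of these targets were higher and 3 lower. Among the lower ones, TGFBR2, a TGF-beta receptor, and CCND1, a G1 cyclin, differed by -0.56 (SE 0.18) and -0.54 (SE 0.18).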

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

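The tests of the column order, the hepatocyte products in the re-ordered column, the random matched lists, the genes listed at 0 and the removal of trends from the site genes were chosen after the data were seen. How many genes the fit with the re-ordered column called was also known before its list medians were tested. The values of knockdown replicate 2 under a re-ordering appear only in this closing section, and the gene of each value rests on that re-ordering, which is a hypothesis.

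Knockdown replicate 2 matched no other column by gene ID. Shallow depth alone is argued against, since knockdown replicate 1 thinned to the same depth kept a rank correlation of 0.776 with control replicate 1. If the re-ordering holds, cells that do not make hepatocyte products are also argued against, since 25 such genes had a median of 0.0637 against the mean of the controls (quartiles -0.49 and 0.27), while another line that makes them was not tested. A candidate explanation is that its values stand in another row order, with chromosomes by decreasing length and genes in the order of GENCODE release 29 within them. In that order 99.9% of its values were whole sixths of a read, against 0.437% by gene ID, and 82.3% whole reads, against 0.285%. Its rank correlation with the other 5 columns was then 0.71 to 0.76. Its depth was then 196129 reads and 151 (3.76%) of 4011 genes with at least 10 reads expected were listed at 0, and the cause of these zeros, or of the fractions of a read that the other 5 columns lack, was not tested.

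In this re-ordered column, which had no part in the comparison of the 5 libraries, 9 of 27 lists had a median above that of every control library and 5 a median below, where chance gives 25% of lists on either side. The hypoxia list, over 22 members with a mean of at least 10 RPKM, had a median of 0.59 against the mean of the controls, and the NF-kB list, over 10 members, a median of 0.74. The others were nuclear-retained and small noncoding RNAs at 0.66, mitochondrially encoded genes at 0.50, immediate early genes at 0.38, fatty acid oxidation at 0.32, TGF-beta and BMP signalling at 0.22, autophagy and lysosome at 0.18, and YAP and matricellular genes at 0.0501. The 5 below were cholesterol synthesis at -0.45, ribosome biogenesis at -0.36, heat shock at -0.30, DNA replication at -0.25 and the NRF2 list at -0.16. For comparison, knockdown replicates 1 and 3 were at 0.58 and 0.58 for hypoxia and 0.66 and 0.57 for NF-kB over the same genes.

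Hypoxia and NF-kB genes were higher, and DNA replication and cholesterol synthesis genes lower, in knockdown replicates 1 and 3. For the hypoxia list, depth is argued against by a median of 0.49 with all 5 libraries thinned to the shallowest. A single library is argued against by a lowest median of 0.47 when each was left out. A trend with gene length or GC is argued against by a median of 0.55 with those trends removed. These tests did not use NF-kB, DNA replication or cholesterol synthesis. Without each library in turn, the medians of those lists ran from 0.48 to 0.80, -0.41 to -0.28 and -0.46 to -0.31. The knockdown is a candidate explanation, since all 4 lists lay on the same side in the re-ordered knockdown replicate 2. That column was not used to find the pattern. Of the other lists past camera in the 5 libraries, cell division, ribosome biogenesis and the NRF2 list also kept their side there. Ribosomal proteins (-0.03), oxidative phosphorylation (-0.09), fatty acid synthesis (0.04) and YAP and matricellular genes (0.05) did not. The rest had too few members at 10 RPKM or more. Among the 4 lists, cholesterol synthesis was at -0.45 (percentile 1.73 of 10000 random lists of matched expression) and DNA replication nearest 0 at -0.25 (percentile 9.96). Hypoxia and NF-kB were above all random lists. The random lists leave out the correlation between members of a list. In the 5 libraries it was estimated at 0.38 for NF-kB, 0.18 for cholesterol synthesis, 0.11 for DNA replication and 0.0047 for hypoxia. Percentiles can therefore overstate how unusual these medians were. Among the 10 splits of the 5 libraries 1, the real one, gave as many as 15 lists and the highest other 13, and 10 splits are too few for a share under 0.05. A culture or handling difference shared by the knockdown libraries stays open, as the labels give no batch, and part of the likeness may come from the shared controls, whose own medians over these genes ran from -0.04 to 0.05 for hypoxia, -0.23 to 0.21 for NF-kB, -0.11 to 0.13 for DNA replication and -0.12 to 0.13 for cholesterol synthesis.

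Genes with a miR-19 site differed by -0.0781 in median, while relief from the microRNA predicts a shift above 0 and among the highest of other orders of the same bases (95th percentile 0.0367), so lower miR-19 activity is argued against as the source of this shift. The genes set against them could still hold TTGCAC, the site without its first base, which can shrink the shift. The sign itself is less certain, since another split of the 5 libraries gave a shift of 0.0777 in size. Of the 419 other orders of the site's bases, 415 gave a higher shift and 6 (1.43%) one as far from 0. The bound written beforehand for 3' UTR length or base composition, 5%, was too lenient. With each library's trends against exon length and transcript GC removed, the shift was -0.0348 and 8.35% of other orders were as far from 0. Those are trends of the whole transcript, and base composition of the 3' UTR alone was not removed. Length or base composition cannot be told apart from an effect of the site, since the trends run along the same genes.

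With the 6 columns as deposited, the real split called 0 genes and the highest other split 0, so that 10 of 10 splits gave as many. A real count of 0 fixes this outcome, which therefore decides nothing about the grouping. For lists the real split gave 1 and the highest other 3, and 5 of 10 splits gave as many. Splits of 3 against 3 are too few for a share under 0.05.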

How the results depend on the processing

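Settings on the 5 libraries, the re-ordered column, voom, thinning and trend removal were chosen after seeing the data. With 6 columns as deposited the count of called genes was 0 under all 12 other settings and without each library. The count of lists was 1, and it was 0 with camera at an estimated correlation and with fry, 25 at a mean RPKM of at least 1, 26 with no filter, 12 without the mean-variance trend, 2 at a pseudocount of 1 and 18 with quantile normalization. It was 17 with the re-ordered column and 16 with that column and the replicate block (1 list, hypoxia, and 0 lists with an estimated correlation), and 0 to 15 without each library in turn (0 without control replicate 3, 2 without control replicate 2, 3 without knockdown replicate 1 or 3, and 15 without knockdown replicate 2). The cause was not tested. Where 1 knockdown library is left, it is assumed to vary like the controls.

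Without knockdown replicate 2 the count of called genes was 0, except 40 with the replicate block (33 higher, 7 lower, 1 residual degree of freedom) and 4 with voom and sample weights. Deviations of same-numbered libraries from their group correlated at -0.17 and 0.02 for replicates 1 and 3. With 2 knockdown libraries the deviations mirror each other, so these values cannot tell whether the numbers pair the libraries. With the block and trends removed 0 genes were called. With the 6 columns the replicate block left 0 genes and 1 list. The count of lists, 15, was 0 with an estimated correlation and 1 with fry, 12 to 15 under the other 14 settings and 14 to 16 without each library. The adjusted p with an estimated correlation was 0.445 for NF-kB (median 0.72), DNA replication (-0.36) and cholesterol synthesis (-0.41) and 0.117 for hypoxia (0.53), and with fry, which tests lists against no change and not against other genes, the first 3 had 0.213. Over all alternatives the adjusted p ran from 8.02e-21 to 0.736 for hypoxia, 2.18e-13 to 0.445 for NF-kB, 1.17e-11 to 0.445 for DNA replication and 1.39e-10 to 0.445 for cholesterol synthesis. Apart from leaving out libraries, calls ended under 10 settings for YAP, 9 for histones, 9 for immune markers and 5 for oxidative phosphorylation, reversals not counted. The miR-17-92 host and regulator list lost its call under 4, and with the re-ordered column its median was -0.19 (adjusted p = 0.0735).

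With knockdown replicate 2 as deposited, whose values did not follow the gene IDs, medians were -1.29 for hypoxia, -0.43 for NF-kB, -1.99 for DNA replication (adjusted p = 0.066), -0.33 for interferon response, -2.67 for ribosomal proteins, -1.88 for oxidative phosphorylation, -0.72 for histones and -0.11 for immune markers, and NPY was at -0.35, UBE2L6 at -0.80 and MIR17HG at -0.19. With the re-ordered column histones were at -0.22, immune markers at -0.11 and MIR17HG at -0.19, listed at 0 there. At the 196129 reads of that column, genes of low RPKM have few or no reads, so these reversals may reflect the floor. MIR17HG had 3 reads in control replicate 2 at 1948940 reads. PSMB9 was at 1.19 with the re-ordered column (2.20 without knockdown replicate 2), AC026401.3 at 0.33 (1.37) and AC131532.1 at -1.70 (-1.02). The miR-19 target median was 0.0701 with trends removed, 0.0329 with trends removed and the replicate block, and -0.310 to 0.0771 without each library, with the value above 0 without knockdown replicate 3. The binned difference of genes with the 7-base site stayed below 0 in all settings run. It was -0.0848 to -0.0258 in 5 libraries, -0.0998 to -0.0459 without each of them, and -0.101 to -0.0349 without each of the 6 columns. Medians without the bins went the other way in some settings. With the 6 columns as deposited they were -1.041 with a site and -1.046 without one. The simulation, with 1 dispersion for all genes, called 8.08% of 2-fold changes at this depth and number of libraries. That share need not hold in the measured libraries, where changes of that size in single genes may have been missed.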

Other observations

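Several single genes outside the leading lists showed separated libraries, although none passed in limma over all genes, and they were chosen after their values were seen. BBC3, which encodes the apoptosis inducer PUMA, was 0.98 (SE 0.17) higher in knockdown replicates 1 and 3, while CDKN1A on the same p53 target list differed by 0.41 (SE 0.25) and the list's median was -0.01. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 1.40 (SE 0.41) higher, and FABP1, a fatty acid binding protein of hepatocytes, 0.84 (SE 0.31) higher. Among hepatocyte products SERPINA1 was 0.54 (SE 0.17) and VTN 0.53 (SE 0.17) higher, with 19 of 29 members above 0 and a median of 0.07. The nuclear-retained RNAs NEAT1 and MALAT1 were 0.65 (SE 0.19) and 0.70 (SE 0.25) higher. IRS1, an adaptor of insulin signalling, differed by -0.75 (SE 0.23) and LIN28B, an RNA-binding protein of fetal liver, by -0.72 (SE 0.21).

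Among other lists, some in the re-ordered column of knockdown replicate 2 went with knockdown replicates 1 and 3 and some did not. Ribosomal proteins were at -0.03 there against 0.23 and 0.51, and fatty acid synthesis genes at 0.04 against -0.18 and -0.46. Oxidative phosphorylation genes were at -0.09 against 0.09 and 0.40, and YAP and matricellular genes at 0.05 against -0.16 and -0.33. Cell division genes were at -0.28 against -0.25 and -0.36, ribosome biogenesis genes at -0.36 against -0.28 and -0.10, the NRF2 list at -0.16 against -0.16 and -0.09, and autophagy and lysosome genes at 0.18 against 0.20 and 0.15. Control replicate 2 overlapped the knockdown libraries at -0.31 for cell division and -0.20 for ribosome biogenesis. For the NRF2 list it was at -0.0957, against -0.0932 in knockdown replicate 3. Immediate early genes were at 0.38 against 0.31 and 0.32, with controls at 0.17, -0.29 and 0.14.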
